A study of Homo sapiens with 11 samples.

How the data were processed

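Gene expression was measured by poly(A) RNA sequencing in 11 libraries of U2OS, a human osteosarcoma cell line, with RNA of Drosophila melanogaster S2 cells added to each as an external standard. Per the labels' protocols, guide RNAs were induced with doxycycline at 1 µg/ml for 4 days, S2 total RNA was mixed with U2OS total RNA before library preparation, a stranded mRNA kit was used, and paired reads of 80 bp were generated. The labels place the libraries in 4 groups, control and TIP60 knockout for each of 2 guide arms (sgRNA1 and sgRNA2), with 3 libraries per group except 2 for the sgRNA1 control. The labels do not say what the control guides target, nor that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

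The deposited files hold counts of reads per human gene and, for the fly standard, per chromosome or scaffold, with 1 library per file. Per the submitters' processing notes, the counts were made by the authors with featureCounts on hg38. The version, the aligner, the annotation release, the strand setting and the fly genome build are not given in the sources used here. The values are whole numbers with different totals per library, and no row lacked a gene or sequence name. The files hold 60715 human gene rows and 1870 fly sequence rows, of which 8 main sequences took 99.8% of the fly counts. Gene symbols were matched for 60445 of the human identifiers (99.6%). Gene types and positions came from GENCODE release 29 on GRCh38, which held 58497 of the identifiers. The column of feature lengths was used only in a check of gene length.

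Human counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 18452 genes, and library sizes were scaled by TMM on human genes, so that fold changes are relative to the rest of the human transcriptome. A quasi-likelihood model with 4 group means was fitted to all 11 libraries. Its contrasts were knockout minus control averaged over both guides, the same within each guide, the difference of the guides' effects, and sgRNA2 control minus sgRNA1 control. P-values were adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05, and all tests were two-sided. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are deposited counts per M of the TMM-scaled library size, computed here. Ratios over nearly empty controls pool the libraries of a genotype and carry 95% Clopper-Pearson intervals, and a control group at 0 was given a floor of 3 counts per group; both cover counting error only.

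A total of 26 gene lists was fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes, except for the tests of the human to fly ratio within guides and between them and the tests of lists between guides, which were added later. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the lists, with camera at an estimated correlation and fry beside it. List members below the expression filter, and 2 histone symbols without a unique identifier (H2AC18 and H3-2), were not tested. The naming rule took KAT5, then the 10 largest rises and 10 largest falls by fitted log2 fold change among genes past the threshold, with a mean log2 CPM of at least 1, a symbol, and every knockout library on the same side of every control library of its guide. In each single guide it took the 5 largest in each direction. In the difference between guides and between controls it took the 5 smallest adjusted p-values in each direction at a mean log2 CPM of at least 1. From each list it took the 4 members with the smallest adjusted p. The report does not name every gene the rule took. The ratio of human to fly counts was compared by an exact two-sided permutation of genotype labels within guides (200 arrangements).

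The model was tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes. In the comparison over both guides, on 17807 simulated genes, 97 of 100 genes changed 2-fold and 86 of 100 changed 1.5-fold were recovered. For sgRNA1 the numbers were 88 and 55, and for sgRNA2 93 and 70. Of the simulated calls, 2.66% were false in the comparison over both guides, 2.72% for sgRNA1 and 8.43% for sgRNA2. The simulation left all other genes unchanged, whereas 12253 of 18452 genes passed in the data, so these rates need not carry over.

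Alternatives were RLE size factors, scaling to the fly total, DESeq2 1.42.0, no expression filter, a minimum count of 50, the replicate number as a block, leaving out each library, models with genotype only or guide plus genotype, and a test against a 1.5-fold change. The human to fly ratio was also computed with median-of-ratios factors. For the fly side these ran over 11 sequences with at least 1000 counts in every library, since fly reads were counted per sequence and not per gene. Thinning to the lowest human total and leaving out genes from KAT5 to the end of 11q were chosen after seeing the data. No 2 libraries held identical values, and replicate pairs differed by 2.77 to 23.8 times the sampling variance per gene.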

Results

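RNA was sequenced from 11 libraries of U2OS osteosarcoma cells, control or knocked out for TIP60 (gene symbol KAT5), the catalytic histone acetyltransferase subunit of the NuA4 complex. The series was set up to compare control with knockout cells, and 2 guide arms allowed the comparison to be made separately in each. There were 2 control and 3 knockout libraries for sgRNA1, and 3 of each for sgRNA2. Human counts per library were 16.7 and 20.9 M in the sgRNA1 controls, and 20.6, 39.1 and 21.96 M in the sgRNA1 knockouts. They were 19.9, 20.3 and 12.9 M in the sgRNA2 controls, and 28.1, 11.2 and 28.7 M in the sgRNA2 knockouts. Fly sequences took between 31.7% and 57.6% of all counts. The first principal component of log2 CPM, with 70.5% of the variance, separated knockout from control libraries, and replicate 2 of the sgRNA2 knockout stood apart on the second, with 6.66%.

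KAT5 (ENSG00000172977.13, chromosome 11, 65711996 to 65719604, GRCh38) was lower in every knockout library than in every control library. In the sgRNA1 arm it fell from 24.98 ± 1.6 CPM (SD, n = 2) to 9.79 ± 0.58 CPM (SD, n = 3), and in the sgRNA2 arm from 24.7 ± 1.8 to 10.2 ± 0.35 CPM (SD, n = 3 each). The fitted log2 fold change over both guides was -1.31 ± 0.08 (SE; edgeR quasi-likelihood test, adjusted p = 3.4e-10), with -1.35 for sgRNA1 and -1.28 for sgRNA2. Counts cover the whole gene, and between 118 and 416 reads per knockout library remained on it. KAT5 lies within a part of chromosome 11 that was lower in knockout cells, described at the end of the gene comparisons.

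**Figure D1:**
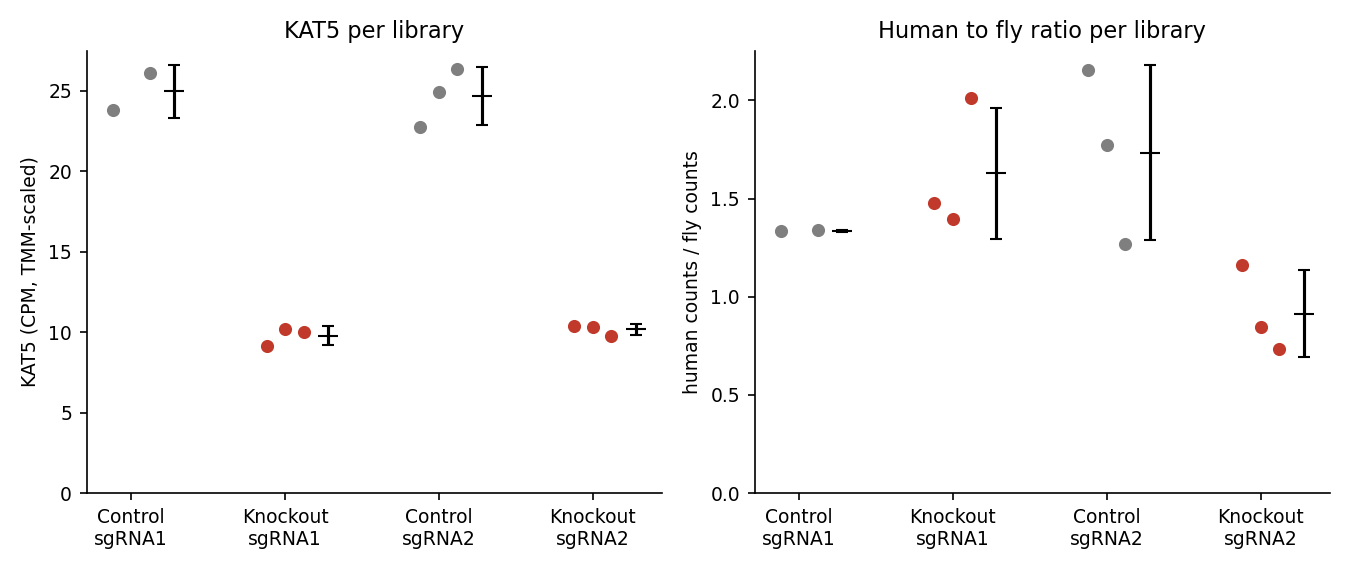
Left, KAT5 in CPM scaled by TMM; right, the ratio of human to fly counts. Points are libraries of the 4 groups, and black bars give the mean and SD. KAT5 lay at 22.8 CPM or above in all controls and at 10.4 CPM or below in all knockouts, whereas the ratio was lower than in controls in the sgRNA2 knockouts only.

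Among genes with a mean log2 CPM of at least 1, those with the largest rises over both guides by the naming rule had few or no reads in control cells. ALPP and ALPG, 2 placental-type alkaline phosphatases, went from 0.778 ± 0.61 to 41.8 ± 15 CPM and from 0.0245 ± 0.035 to 4.42 ± 1.6 CPM in the sgRNA1 arm (SD, n = 2 and 3), and from 0.571 ± 0.18 to 45.0 ± 6.5 CPM and from 0.0357 ± 0.062 to 3.85 ± 0.83 CPM in the sgRNA2 arm (SD, n = 3 each). These copies are nearly identical, so reads shared between them make the single values uncertain. GLP2R, the receptor of glucagon-like peptide 2, rose to 3.72 ± 0.71 CPM with sgRNA1 and 3.28 ± 0.37 CPM with sgRNA2, and UNC13A, a presynaptic vesicle-priming factor, to 4.68 ± 0.46 and 4.33 ± 0.57 CPM. Neither had a read in the sgRNA2 controls, which makes GLP2R at least 54.7-fold and UNC13A at least 72.2-fold higher in that arm against the floor of 3 counts. SAA1, an acute-phase apolipoprotein with close copies in the genome, reached 3.21 ± 0.84 and 5.44 ± 1.9 CPM, and SNAP25, a neuronal SNARE protein, 2.90 ± 0.22 and 3.35 ± 0.37 CPM.

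TMEM132B, the chorionic gonadotropin gene CGB8, IGFN1 and the protocadherin FAT3 completed the 10 rises taken by the naming rule. Pooled over libraries, IGFN1 had 26 control and 1362 knockout reads, a ratio of 28.8 (95% Clopper-Pearson interval 19.6 to 44.3), and FAT3 13 and 684 reads, a ratio of 28.97 (16.8 to 54.7). For TMEM132B the ratio was 47.7 (21.8 to 131), and for CGB8, which shares reads with its copies, 29.01 (15.7 to 60.9). These intervals cover counting error only. FAT3 lies beyond KAT5 on chromosome 11. The adjusted p of the 20 changes taken by the rule was at most 7.1e-08 (edgeR).

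Falls were smaller than the largest rises. SLITRK5, a neuronal transmembrane protein, fell most by the naming rule, from 24.6 ± 0.45 to 4.24 ± 0.57 CPM with sgRNA1 (SD, n = 2 and 3) and from 25.5 ± 3.5 to 3.50 ± 0.21 CPM with sgRNA2, a log2 fold change of -2.70 ± 0.10. WNT10B, a secreted WNT ligand, followed at -2.39 ± 0.19. LRFN4 (-2.23 ± 0.10), the nucleoside transporter SLC29A2 (-2.21 ± 0.11), CLMP (-2.18 ± 0.15) and C11orf80 (-2.16 ± 0.13) all lie beyond KAT5 on chromosome 11. EVA1C (-2.14 ± 0.12), the homeobox gene MKX (-2.13 ± 0.20) and PYCR1, a proline synthesis enzyme (-2.06 ± 0.09), lie on other chromosomes.

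In all, 12253 of 18452 genes passed the threshold over both guides, 6387 higher and 5866 lower in knockout cells (edgeR, adjusted p under 0.05). Of these, 2885 rose and 625 fell by at least 1 on the log2 scale. Of all genes tested, called or not, 9485 (51.4%) had every knockout library on the same side of every control library in both guides, where chance order gives 1%. When libraries were scaled to the fly total instead, 7705 genes passed, 3256 higher and 4449 lower, and the median log2 fold change of all genes moved from 0.01 to -0.17. Tested against a 1.5-fold change, 4352 genes passed, 3053 higher and 1299 lower.

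Some gene lists mostly fell, some mostly rose, and others, such as the p53 targets, went both ways. Fold changes also varied with expression level. The median was 0.50 for 5082 genes under a mean log2 CPM of 1. It was -0.26 for 1878 genes above 7, of which 1076 fell and 383 rose. The lists were not compared with genes of like level, so level may account for part of their changes. Of the 26 lists, 13 passed camera at the preset correlation, 10 lower and 3 higher, and none passed with an estimated correlation, where the smallest adjusted p was 0.165. All 103 list members taken by the naming rule, most of them named below, passed in the comparison over both guides (edgeR, largest adjusted p = 0.0320), with standard errors of 0.05 to 0.53 on the log2 scale. They were taken for the smallest adjusted p in this same comparison, which 66.4% of all tested genes passed. Their passing is therefore no evidence for a list. Rotation tests with fry, which ask whether a list changed at all and not whether it changed more than other genes, passed for 21 lists. Values are log2 fold changes over both guides, relative to the human transcriptome.

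Among genes of ribosome biogenesis 21 of 22 fell and 1 rose, with the same counts when adjusted over the list alone, and a median of -0.65 (camera adjusted p = 4.3e-07, adjusted p = 0.165 with an estimated correlation). NOP16 (-1.19), POLR1B (-1.12), WDR12 (-1.09) and WDR43 (-1.003) fell most clearly. Of the cytosolic ribosomal proteins 25 of 26 fell, 26 when adjusted over the list alone, with a median of -0.64 (camera adjusted p = 1.0e-06, adjusted p = 0.472 with an estimated correlation). RPS3 (-0.94, beyond KAT5 on chromosome 11), RPL3 (-0.85), RPL10A (-0.81) and RPL5 (-0.75) were among them; processed copies of these genes elsewhere make single values uncertain. Mitochondrial ribosomal proteins fell in 11 of 18 cases and rose in 2, also over the list alone, with MRPL15 (-0.92), MRPL3 (-0.74), MRPL17 (-0.69) and MRPS34 (-0.53) (camera adjusted p = 0.0423, adjusted p = 0.567 with an estimated correlation). This call ended without replicate 3 of the sgRNA1 knockout (camera adjusted p = 0.0546) or replicate 1 (0.0653) or 3 (0.0591) of the sgRNA2 knockout, within a range of 0.0116 to 0.567 over all alternatives.

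In the G2/M and mitosis list 21 of 24 fell and none rose, also over the list alone, with a median of -0.51 (camera adjusted p = 6.3e-05, adjusted p = 0.472 with an estimated correlation). The kinase PLK1 (-1.10), the checkpoint protein BUB1B (-1.06), CDC20 (-0.83) and cyclin CCNB1 (-0.76) were among them. Of 31 DNA replication and G1/S genes 23 fell and 4 rose, 24 and 4 over the list alone (camera adjusted p = 0.00108, adjusted p = 0.472 with an estimated correlation), among them the licensing factors MCM2 (-0.90) and CDT1 (-0.87) and the clamp loader subunits RFC2 (-0.72) and RFC3 (-0.67). Of 7 listed CDK inhibitors, CDKN1C, CDKN2A and CDKN2B were below the expression filter and not tested. All 4 CDK inhibitors tested rose, also over the list alone, namely CDKN1A (1.89), CDKN2C (1.21), CDKN2D (0.51) and CDKN1B (0.28) (camera adjusted p = 0.0423, adjusted p = 0.472 with an estimated correlation). This call ended without replicate 3 of the sgRNA1 control (camera adjusted p = 0.0510), of the sgRNA1 knockout (0.0512) or of the sgRNA2 control (0.0526), and without replicate 1 (0.0504), 2 (0.0624) or 3 (0.0523) of the sgRNA2 knockout, within a range of 0.0191 to 0.472 over all alternatives.

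In the p53 target list members went both ways: 8 of 23 rose and 6 fell, 7 and 6 over the list alone, and the list did not pass (camera adjusted p = 0.739). CDKN1A (1.89) and TP53INP1 (2.13) rose, whereas MDM2, which degrades p53 (-1.31), and the nuclease AEN (-1.14) fell. Of 25 genes of homologous recombination and Fanconi repair 16 fell and 1 rose, also over the list alone (camera adjusted p = 0.00177, adjusted p = 0.472 with an estimated correlation). The end-resection factor RBBP8 (-1.08), FANCA (-0.92), RAD51D (-0.61) and the checkpoint kinase CHEK1 (-0.53) fell; CHEK1 lies beyond KAT5 on chromosome 11.

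In the TIP60/NuA4 complex 13 of 18 subunit genes fell and 2 rose, also over the list alone (camera adjusted p = 0.0168, adjusted p = 0.165 with an estimated correlation), with MRGBP (-1.13), MEAF6 (-0.81) and MORF4L2 (-0.68) beside KAT5. Of 9 genes for H2A.Z and its exchange 6 fell and none rose, also over the list alone (camera adjusted p = 0.0168, adjusted p = 0.165 with an estimated correlation). ANP32E, the chaperone that removes H2A.Z, fell by 1.71, and INO80 (-0.71), H2AZ1 (-0.53) and EP400 (-0.37) fell less. Other histone acetyltransferases fell in 6 of 10 cases and rose in 1, 7 and 1 over the list alone, but the list did not pass (camera adjusted p = 0.0777); CREBBP (-0.78), KAT7 (-0.69), KAT2A (-0.57) and EP300 (-0.46) fell. Of 9 replication-dependent and linker histone genes read from polyadenylated RNA 8 rose and 1 fell, also over the list alone, with a median of 1.79 (camera adjusted p = 0.00083, adjusted p = 0.306 with an estimated correlation). H2BC5 (3.23), H2BC21 (2.72), H2AC6 (2.40) and H2BC12 (1.55) rose; coding sequences of these genes resemble one another, which makes single values uncertain.

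In cholesterol synthesis 15 of 20 genes fell and 1 rose, also over the list alone, with a median of -0.54 (camera adjusted p = 0.00031, adjusted p = 0.439 with an estimated correlation). CYP51A1 (-1.34), DHCR7 (-1.12, beyond KAT5 on chromosome 11), the transcription factor SREBF2 (-0.91) and FDPS (-0.84) fell. Of the nuclear-encoded respiratory chain 11 of 22 fell and 2 rose, 9 and 2 over the list alone (camera adjusted p = 0.0311, adjusted p = 0.559 with an estimated correlation), with NDUFS1 (-0.59), ATP5F1B (-0.49) and UQCRC2 (-0.42) lower and SDHC (0.62) higher. This call ended without replicate 1 of the sgRNA2 knockout (camera adjusted p = 0.0653, range over all alternatives 0.00319 to 0.559). Of 13 mitochondrially encoded mRNAs 4 rose and none fell, also over the list alone, and the list did not pass (camera adjusted p = 0.217); MT-ND6 (0.78), MT-ND5 (0.68), MT-CYB (0.52) and MT-ND1 (0.48) rose. Without replicate 1 of the sgRNA1 control, MT-CYB (adjusted p = 0.0716, edgeR; range over alternatives 3.7e-13 to 0.887) and MT-ND1 (0.0848; 6.2e-11 to 1) no longer passed. Of 14 housekeeping genes 9 fell and 1 rose, also over the list alone (camera adjusted p = 0.0719). HPRT1 (-0.48) and YWHAZ (-0.41) were among those that fell. The housekeeping list passed as lower without replicate 3 of the sgRNA1 control (camera adjusted p = 0.0328) or replicate 2 of the sgRNA2 knockout (0.0465), with a range of 0.0328 to 0.472 over all alternatives.

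Stress lists did not pass as sets. Of 17 ATF4 targets of the integrated stress response 6 fell and 2 rose, also over the list alone (camera adjusted p = 0.387), with TRIB3 (-1.07), PSAT1 (-0.67) and SHMT2 (-0.62) lower and ATF5 (0.50) higher. Of 15 genes of the ER unfolded protein response 8 fell and 2 rose, 9 and 2 over the list alone (camera adjusted p = 0.148), with XBP1 (-0.85), HYOU1 (-0.53, beyond KAT5 on chromosome 11) and EDEM1 (-0.47) lower and SEL1L (0.46) higher. Both lists moved with a single control library. Without replicate 1 of the sgRNA1 control both passed as lower (camera adjusted p = 0.0156 and 0.00556), and without replicate 3 the median of the ATF4 targets relative to all genes turned from -0.37 to 0.19. Over all alternatives the adjusted p ranged from 0.0156 to 0.780 for ATF4 targets and from 0.00556 to 0.730 for the unfolded protein response.

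In the extracellular matrix and osteoblast list 9 of 10 tested genes rose, also over the list alone (camera adjusted p = 0.00177, adjusted p = 0.165 with an estimated correlation), with fibronectin FN1 (1.68), COL5A2 (1.31), COL6A1 (1.10) and the osteoblast transcription factor RUNX2 (0.66). The list held 20 genes, so these values cover only a part of it. Genes below the expression filter were COL1A2, COL3A1, POSTN, BGN, DCN, SP7, ALPL, SPP1, IBSP and BGLAP. Of 19 autophagy and lysosome genes 11 rose and 4 fell, also over the list alone (camera adjusted p = 0.0949), with the autophagy receptor SQSTM1 (0.88) and MAP1LC3B (0.88) higher and TFE3 (-0.81) and UVRAG (-0.72, beyond KAT5 on chromosome 11) lower. Leaving out genes from KAT5 to the end of the arm brought this list past the threshold (camera adjusted p = 0.0433, range over all alternatives 0.0433 to 0.758). Of 17 senescence-associated secretory factors 7 rose and 1 fell, also over the list alone (camera adjusted p = 0.0946); MMP3 (2.39), on the same part of chromosome 11, IGFBP3 (1.72), IGFBP7 (1.45) and CSF2 (1.11) rose.

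Of 15 YAP/TEAD targets 8 rose and 5 fell, also over the list alone (camera adjusted p = 0.353), with TGFB2 (2.54) and ANKRD1 (1.19) higher and FJX1 (-0.86) and ARHGEF17 (-0.73, beyond KAT5 on chromosome 11) lower. Of 18 interferon-stimulated genes 8 rose and 3 fell, also over the list alone (camera adjusted p = 0.106), with OAS1 (1.88), IFI6 (1.42), IFIT2 (0.80) and IFIH1 (0.65). In the WNT list 5 of 8 rose and 2 fell, 5 and 3 over the list alone (camera adjusted p = 0.355), with LGR5 (2.85), APCDD1 (2.07), TCF7 (1.07) and DKK1 (0.77). Of 7 epithelial markers 1 rose and 3 fell, also over the list alone (camera adjusted p = 0.491), with KRT8 (0.53) higher and KRT19 (-0.79), CLDN7 (-0.51) and KRT18 (-0.36) lower. Of 4 leukocyte markers past the expression filter 3 rose and 1 fell, also over the list alone (camera adjusted p = 0.0949), with PTPRC (3.97) and CORO1A (0.53) higher and LCP1 (-0.28) lower. LCP1 no longer passed without any 1 of 7 libraries (replicate 3 of the sgRNA1 control, -0.11, adjusted p = 0.435, edgeR; replicates 2, -0.27, 0.0729, and 3, -0.24, 0.0957, of the sgRNA1 knockout; replicates 2, -0.26, 0.0753, and 3, -0.21, 0.121, of the sgRNA2 control; replicates 2, -0.24, 0.0685, and 3, -0.29, 0.0545, of the sgRNA2 knockout), with a range of 0.00278 to 1 over all alternatives. ITGAM had 2 control and 173 knockout reads, a pooled ratio of 47.6 (95% Clopper-Pearson interval 13.0 to 396). The other 6 leukocyte markers stayed below the filter, and CD14 had 12 control and 58 knockout reads.

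Scaling to the fly total ended the calls of 14 of the list members taken by the naming rule, with adjusted p between 0.0603 and 0.773 (edgeR). Among them were CDKN2D, CDKN1B, SDHC, MT-ND5, MT-CYB, MT-ND1, ATF5, SEL1L, IFIH1, RUNX2, KRT8, CORO1A and LCP1. It also ended the camera calls of 6 lists, the TIP60/NuA4 complex, H2A.Z, the CDK inhibitors, mitochondrial ribosomal proteins, the respiratory chain and the extracellular matrix, with camera adjusted p between 0.0551 and 0.106, while leukocyte markers passed (0.00067, range over all alternatives 0.00067 to 0.439). The medians of these 6 lists relative to all genes hardly moved, from -0.31 to -0.32, -0.31 to -0.32, 0.85 to 0.83, -0.25 to -0.26, -0.19 to -0.21 and 0.69 to 0.69 in the order given.

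**Figure D2:**
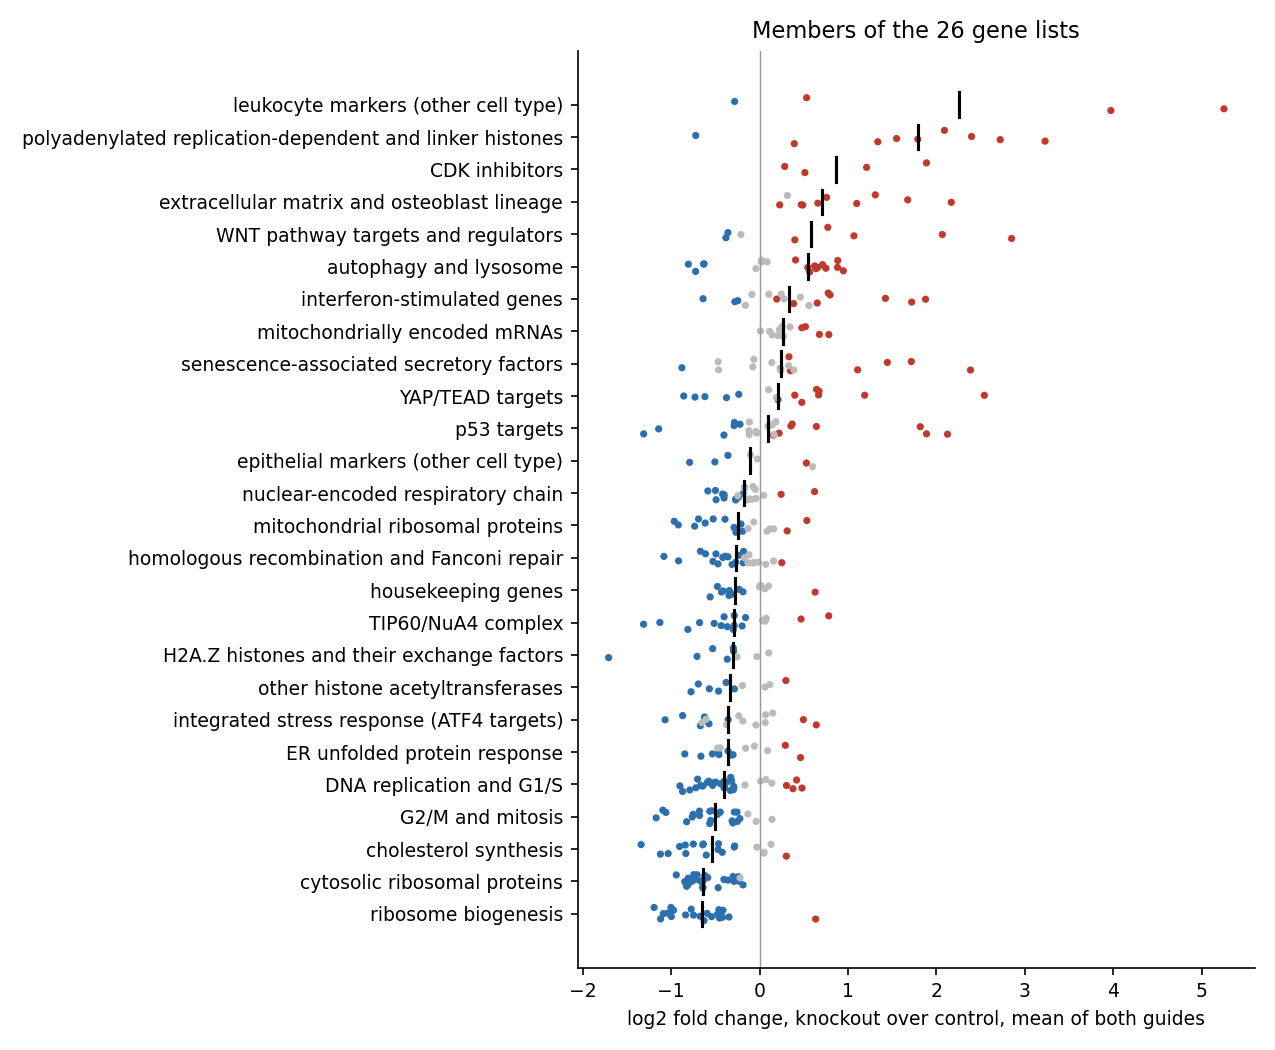
Log2 fold change over both guides for each tested member of the 26 lists, 1 point per gene, red for called rises, blue for called falls and grey for genes that did not pass (edgeR, adjusted p under 0.05). Black lines are list medians, lowest for ribosome biogenesis at -0.65 and highest for leukocyte markers at 2.25, the latter over 4 genes.

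The 2 guides were compared with separate controls. In the sgRNA1 arm 8938 genes passed, 4483 higher and 4455 lower, and in the sgRNA2 arm 10829, 5768 higher and 5061 lower (edgeR). By the naming rule the largest rises were ALPG, SAA1, GLP2R, ALPP and IGFN1 with sgRNA1 and UNC13A, GLP2R, TMEM132B, CGB8 and ALPG with sgRNA2. By the same rule the largest falls were SLITRK5, C11orf80, LRFN4, SLC29A2 and ADM2 with sgRNA1, and with sgRNA2 they included SLITRK5, WNT10B, CLMP and LRFN4. ADM2, a calcitonin-family peptide hormone, had a log2 fold change of -2.19 in the sgRNA1 arm, which no longer passed without replicate 3 of the sgRNA1 control (-0.85, adjusted p = 0.0640, edgeR; range over alternatives 8.1e-36 to 0.0640). With fly scaling the sgRNA1 arm gave 3497 higher and 158 lower genes, with a median of 0.40, and the sgRNA2 arm 1417 higher and 8950 lower, with a median of -0.73.

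Across genes, which are not independent replicates, the log2 fold changes of the guides correlated with Pearson r = 0.87 and Spearman rho = 0.88. Rises were shared by 4078 genes and falls by 3826, where independent lists would share 1401 and 1222. Opposite calls were made for 4 genes, named after their values were seen: ATP23 (-1.28 with sgRNA1 and 1.47 with sgRNA2), B9D1 (-0.41 and 0.37), NLRX1 (-0.54 and 0.40, beyond KAT5 on chromosome 11) and the antisense gene VLDLR-AS1 (-1.02 and 1.08), none of which passed for the difference itself. No gene passed for a difference between the guides' effects by edgeR, where the smallest adjusted p was 0.729 and 1213 genes had an unadjusted p under 0.05; DESeq2 called 1, the pseudogene HSPD1P1 (-0.54 ± 0.11, adjusted p = 0.0126), named after its value was seen. With no expression filter the correlation was 0.43 and 40 genes differed, without replicate 1 of the sgRNA1 control 32 differed, and with fly scaling 9415.

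**Figure D3:**
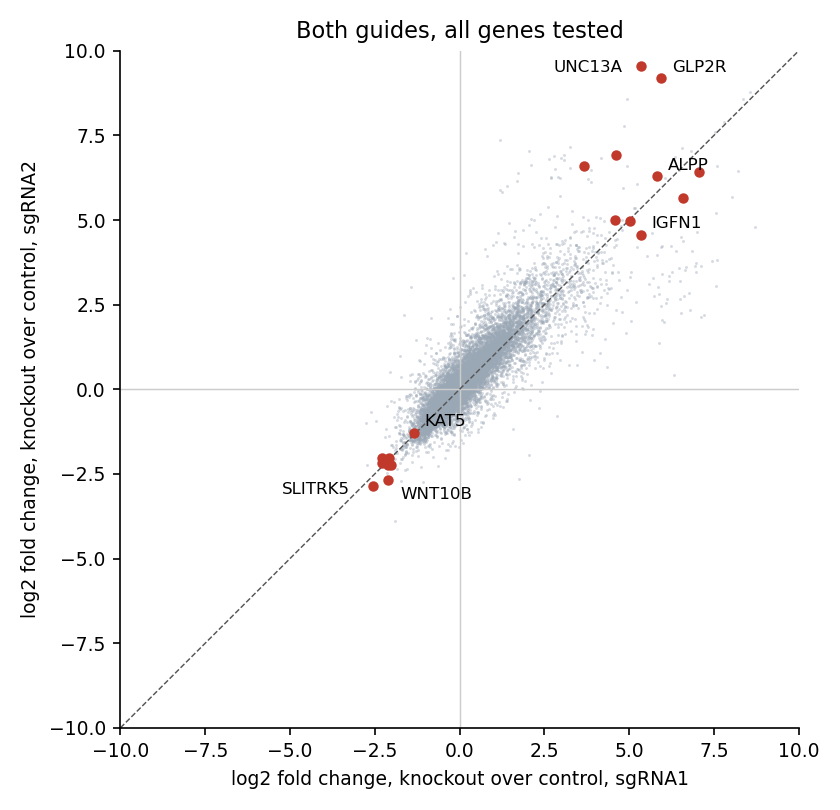
Log2 fold change of knockout over control in the sgRNA1 arm (x axis) and sgRNA2 arm (y axis) for the 18452 genes tested, with KAT5 and the 20 changes taken by the naming rule in red and the line of equal change dashed. Points follow the line with r = 0.87; fitted values of GLP2R and UNC13A on the y axis depend on control groups without reads.

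The 2 control groups differed in 3 genes (edgeR), all with a mean log2 CPM under 1 and named after their values were seen. The chemokine receptor ACKR4 was at 3.39 ± 0.82 CPM (SD, n = 2) in sgRNA1 controls and 0.327 ± 0.21 CPM (SD, n = 3) in sgRNA2 controls (adjusted p = 0.00606, edgeR). ZBTB20-AS5, an antisense gene whose values are uncertain because the strand setting of the counting is not given in the sources used here, was at 1.13 ± 0.065 and 0 CPM (adjusted p = 0.0212, edgeR), and the pseudogene HMGB1P33 at 0.969 ± 0.016 and 0 CPM (0.0226). The sgRNA2 knockouts also had no read of ZBTB20-AS5 or HMGB1P33, whereas the sgRNA1 knockouts had 1.33 ± 0.33 and 0.937 ± 0.21 CPM (SD, n = 3). DESeq2 called 21 genes. By edgeR, leaving out replicate 1 of the sgRNA1 control gave 104 and replicate 2 of the sgRNA2 knockout 6, while without replicate 3 of the sgRNA1 control 1 gene passed, ENSG00000234648, which is none of the 3. Without replicate 2 or 3 of the sgRNA2 control ACKR4 alone passed, and without replicate 1 none did (0 genes by edgeR, 1659 at an unadjusted p under 0.05).

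Genes along chromosome 11 were lower beyond KAT5. Among protein-coding genes with a mean log2 CPM of at least 1, the 316 beyond KAT5 had a median log2 fold change of -0.47 (95% bootstrap interval -0.53 to -0.37), against -0.06 for 10647 genes on other chromosomes and -0.05 (-0.16 to 0.03) for 204 genes before 50 Mb on chromosome 11. The median was -0.52 with sgRNA1 and -0.40 with sgRNA2. Beyond KAT5 64.6% of genes fell and 15.8% rose, compared with 40.1% and 31.7% on other chromosomes. The 118 genes in the 10 Mb before KAT5 had a median of -0.33 (-0.40 to -0.20). These intervals are over genes, which are not independent replicates.

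**Figure D4:**
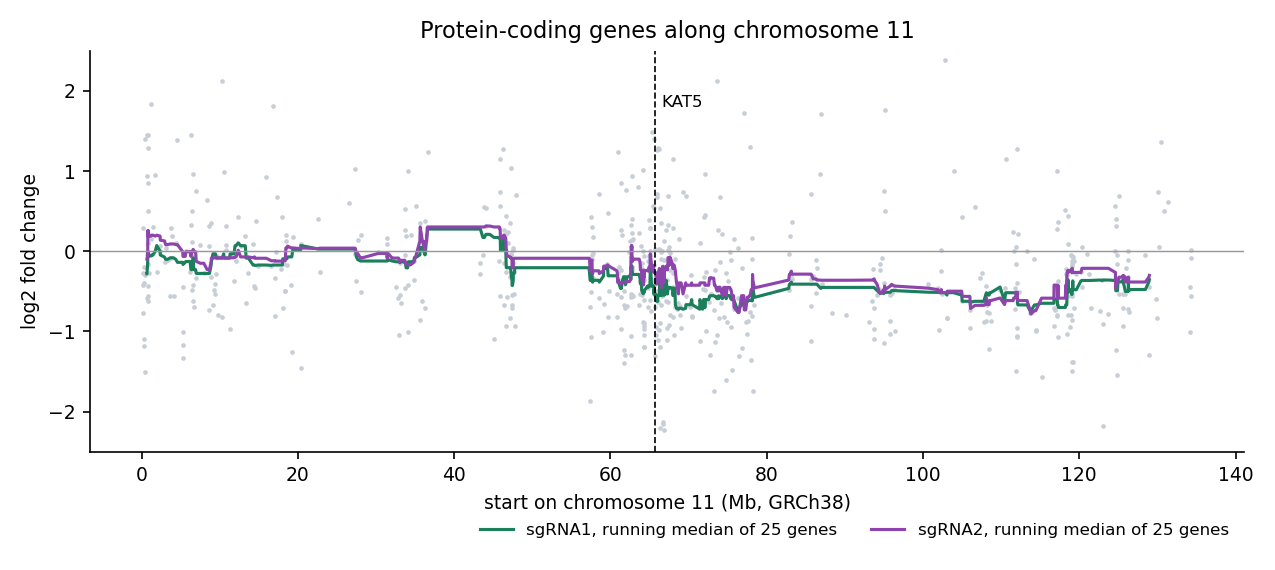
Log2 fold change over both guides of 639 protein-coding genes (grey points, mean log2 CPM of at least 1) by their start on chromosome 11 in Mb on GRCh38, with running medians of 25 genes for each guide; 9 genes lie outside the axis. Both lines lie below 0 beyond KAT5 (dashed line), where the median is -0.52 with sgRNA1 and -0.40 with sgRNA2.

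The ratio of human to fly counts gives human mRNA per added fly RNA. It was 1.34 ± 0.0055 (SD, n = 2) in sgRNA1 controls and 1.63 ± 0.34 (SD, n = 3) in sgRNA1 knockouts, and 1.73 ± 0.44 and 0.914 ± 0.22 in the sgRNA2 arm (SD, n = 3 each). The mean log2 change over both guides was -0.33 and did not pass (exact permutation test within guides, two-sided, p = 0.26). Within sgRNA1 the change was 0.27 (exact permutation p = 0.3), and within sgRNA2 -0.92 (exact permutation p = 0.1), where neither arm can give a p below 0.1. The changes of the 2 guides differed by -1.18 on the log2 scale (exact permutation p = 0.015, 200 arrangements). This test permutes genotype labels in both arms, so its null is no change in either arm, not equal changes. A change in a single arm could pass it, so it does not show that the guides differ. The tests within each guide and of their difference were chosen after the ratios were seen.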

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

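The tests of the human to fly ratio between guides and of its explanations, and the tests of lists between guides, were chosen after the results were seen, whereas the regrouping of libraries was planned.

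The ratio of human to fly counts moved up with sgRNA1 and down with sgRNA2, and the 2 changes differed by -1.18 on the log2 scale (exact permutation test within guides, two-sided, p = 0.015). The null of this test is no change in either arm, not equal changes, so a change in a single arm could pass it. All 3 sgRNA2 knockouts lay below all 3 sgRNA2 controls, and all 3 sgRNA1 knockouts above both sgRNA1 controls. One common change of mRNA yield after TIP60 loss stays open, since this exact permutation test (p = 0.015) measures the pattern it was chosen from; its p was 0.05 and thus not below the threshold without replicate 1 of the sgRNA2 control, replicate 2 or replicate 3 of the sgRNA2 knockout, and otherwise between 0.015 and 0.0375. Amounts of fly RNA that differed between groups cannot be told apart from a change of human mRNA relative to human total RNA, since no second standard was counted; the highest ratio was 1.70 times the lowest within the sgRNA2 controls alone. A difference between the guides in their effect on the cells stays open as an explanation of the ratio. With TMM scaling 0 of 18452 genes passed for a difference between guides (edgeR). That scaling removes a change common to all genes, so it does not decide this.

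The count of genes changed over both guides was compared with other ways of grouping the same libraries within guides. Of 100 splits drawn from 200, 1 gave as many genes, the real one with 12253. Regrouping of libraries cannot exclude a chance difference between cultures, since the labels do not say that replicates were separate cultures. The highest other split gave 8997 genes and was close to a mirror of the real one, with 1 of the 3 sgRNA1 knockouts and 0 of the 3 sgRNA2 knockouts kept. For sgRNA2, 10 splits are too few for a share under 0.05; the real split gave 10829 genes and the highest other 0.

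For 9 gene lists camera at the preset correlation also found a difference between the guides, given here as the median effect of sgRNA2 minus sgRNA1. It was positive for ATF4 targets (0.56), the unfolded protein response (0.53) and cytosolic ribosomal proteins (0.22). It was negative for histones (-0.26), G2/M genes (-0.20), H2A.Z and its exchange factors (-0.16), other histone acetyltransferases (-0.13), homologous recombination (-0.0805) and ribosome biogenesis (-0.0683). None of the 26 lists passed with an estimated correlation, where the smallest adjusted p was 0.649, or by fry, where it was 0.221. In the comparison over both guides, ATF4 targets and the unfolded protein response moved with a single sgRNA1 control library. Single control libraries may therefore contribute to the differences of these lists between guides.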

How the results depend on the processing

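Thinning to the lowest human total and leaving out genes from KAT5 to the 11q end were tests chosen after the results were seen; the other alternatives were planned. KAT5 stayed lower and past the threshold under all 21 alternatives (-1.49 to -1.25; adjusted p 3.8e-46 to 1.4e-07, edgeR or DESeq2). With fly scaling the counts were 7705 over both guides, 3655 for sgRNA1, 9415 for the difference between guides, 8 between controls and 8 gene lists; the scaling by construction moves all genes of a library together, so the medians shift. Against a 1.5-fold change 4352 genes passed, a stricter test by construction. With no expression filter 40 genes differed between guides and 152 between controls, and the guides correlated with r = 0.43; with a minimum count of 50, 1 gene differed between controls; DESeq2 gave 1 and 21; the cause was not tested. With an estimated correlation 0 lists passed. Leaving out single libraries gave 11496 to 12692 genes over both guides, 6925 to 9836 for sgRNA1, 9560 to 11261 for sgRNA2, 0 to 32 for the difference between guides (32 without replicate 1 of the sgRNA1 control), 0 to 104 between controls (104 without replicate 1 of the sgRNA1 control, 6 without replicate 2 of the sgRNA2 knockout, 1 or 0 without any other control library), r from 0.781 to 0.878, 10 to 15 lists and a ratio change of -0.43 to -0.24; where 1 sgRNA1 control remained it was assumed to vary like the other groups. Relative to all genes, the median of ATF4 targets ran from -0.57 without replicate 1 to 0.19 without replicate 3 of the sgRNA1 control; the cause was not tested. Equal numbers were taken to share only a number: the 5 same-number pairs of control and knockout within a guide correlated between -0.08 and -0.01, and 0 of the 10 libraries in these pairs correlated best with their own number. Across guides the controls numbered 1 correlated at 0.185 and those numbered 3 at 0.102. Knockouts numbered 1, 2 and 3 correlated across guides at 0.0493, 0.0216 and 0.0443. The 2 sgRNA1 controls correlated with any other library at opposite signs, so their values are not independent checks. With a replicate block the counts were 12112, 8484, 10685, 0 and 2, with r = 0.866, 13 lists and KAT5 at -1.32. Thinned, 10727, 7697 and 9533 genes passed; without the 11q genes 11934 genes and 14 lists. For 142 results of named genes, 68 of 2899 values no longer passed, 41 of them against a 1.5-fold change and 14 with fly scaling, and 0 reversed. For lists, 29 of 390 values no longer passed, 6 newly passed and 1 reversed. With every library thinned to the lowest human total, 11.2 M, 16549 genes could be tested in place of 18452.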

Other observations

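The tests of chromosome 11, of fly reads and of leukocytes were chosen after the results were seen, as were the genes named in this part; the test of depth was written before its result was seen. A set of 302 genes lay under 0.5 CPM in both control groups and at 1 CPM or above in both knockout groups, 205 of them protein-coding and 75 long noncoding. The glutamate transporter SLC1A7 had no control reads and reached 2.10 and 2.42 CPM, surfactant protein SFTPC 1.76 and 1.48 CPM, myoglobin MB 1.25 and 1.796 CPM, the B-cell factor PAX5 1.65 and 1.46 CPM, von Willebrand factor VWF 2.04 and 2.10 CPM and the calcitonin receptor CALCR 3.25 and 3.25 CPM with sgRNA1 and sgRNA2. The opposite pattern held for 5 genes, FAM166C, DNAH17-AS1, RBM44, ENSG00000265511 and ENSG00000261208.

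Gene classes differed too, though they were not matched for expression level. Of 980 long intergenic noncoding genes 561 rose and 66 fell (edgeR, median log2 fold change 0.72), and of 1134 antisense genes, which are uncertain because the strand setting is not given, 530 rose and 106 fell (0.52). Of 1790 processed pseudogenes 133 rose and 768 fell (-0.37), whereas 13119 protein-coding genes had a median of -0.01. Processed pseudogenes resemble the genes they were copied from, so shared reads make their values uncertain. Below a mean log2 CPM of 1, 2222 genes rose and 493 fell (median 0.50), and above 7, 383 rose and 1076 fell (-0.26). Effects of class and of level were thus not told apart.

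Deeper knockout libraries could make weak genes appear, as they held 27.2 and 22.7 M human counts on average against 18.8 and 17.7 M, but at the lowest human total 99.7% of the 302 genes (301) were still called as rises. Fly reads counted on human genes would move with the fly share, which was not higher in sgRNA1 knockouts than in their controls, yet 555 genes picked from sgRNA2 alone had a median log2 fold change in sgRNA1 of 2.08 (95% bootstrap interval 1.94 to 2.25). Leukocyte genes are among the 302, such as ITGAM, ITGAX (2.27 and 2.32 CPM), LCK (1.74 and 2.39 CPM) and CCR7 (1.24 and 1.48 CPM). Admixed leukocytes stay open as their source: 6 other markers rose together by 0.317 and 0.339 CPM, at most 11.9% of the rise of PTPRC by 3.58 and 2.85 CPM, but these 6 are the list members below the expression filter, which a marker that rose strongly would have passed, so a low sum decides nothing. A candidate explanation that also stays open is wider transcription of silent genes after TIP60 loss, and no chromatin measurement was analysed here.

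Expression beyond KAT5 on chromosome 11 was lower than in any of 4259 equally long runs of neighbouring genes on 17 other chromosomes. Of these runs 0% were as low, and the lowest was at -0.17, but the runs overlap and are not independent. Loss of the segment from KAT5 to the 11q end in part of the cells may contribute. Loss of the whole of chromosome 11 is argued against by genes before 50 Mb, whose median lay 0.41 (0.26 to 0.52) above, and gene level or length by a median of -0.46 (-0.51 to -0.37) after their trend was removed. The 10 Mb before KAT5 also lay -0.28 (-0.38 to -0.09) from the genes before 50 Mb. A segment whose border is the KAT5 cut site alone would leave those 10 Mb unchanged. They were not compared with runs elsewhere or corrected for level and length, so the border stays undecided. Genes beyond KAT5 lay a further -0.13 (-0.29 to -0.01) from those 10 Mb. All intervals in this paragraph are over genes, which are not independent replicates, and do not cover the spread between libraries. Regulation of this region by TIP60 stays open. The labels do not say what the control guides target, so no control is known to have a break on 11q with intact TIP60. The falls of LRFN4, SLC29A2, CLMP and C11orf80 (-2.16 to -2.23) exceed the regional median of -0.47, so the region may account for part of them and leaves the rest unexplained.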
